A study of Synechocystis sp. PCC 6803 with 13 samples.

How the data were processed

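RNA from 13 cultures of Synechocystis was measured on 13 one-colour Agilent arrays, 1 per culture, after direct labelling of the RNA with Cy3 and without cDNA synthesis, so signals are strand-specific. Per the labels the arrays are biological replicates. The scanner files hold spot intensity values, which per the file headers were background-subtracted and spatially detrended by Agilent Feature Extraction 10.7.3.1 and not normalized between arrays. The series table holds log2 values which, as deposited by the authors, were made with limma (no version stated) without background subtraction. Their quantiles are nearly equal between arrays, with a median of 12.133 in every column, and their ranks equal those of the raw median signal (rank correlation 1). The scanner intensities were the starting point here, and the series table served as an alternative.

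Each array held 42303 spots, of which 1417 were controls and 40886 were used. Spots with an outlier mark, 2 to 309 per array, were left out, duplicate spots and then probes of a feature were averaged, and log2 signals were expressed relative to the array's 75th percentile over non-control spots. A feature was tested when a probe of it was well above background on every array of at least 1 group and each group had a value, which left out 520 dim features and 2 without a usable spot. The features with locus tags are protein-coding mRNAs, and suffixes such as -as, -int and -x come from the array design, whose meaning beyond antisense and internal the files do not give. The 75th percentile per array was 4157 to 7313 and the local background 23 to 36 brightness units, and the SD of duplicate spots was 0.118 to 0.171 on the log2 scale.

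All 13 arrays entered 1 limma fit of group means with an intensity trend in the prior variance, with 7 residual degrees of freedom and a median of 2.83 prior ones. The 11 comparisons were each strain at 3 h and 24 h against high CO2 and at 24 h against 3 h, the mutant against the wild type at each condition, and the difference of the strains' responses at 3 h and 24 h. Samples were not treated as paired, since equal replicate numbers are not stated to share a culture. A feature was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested features of a comparison, two-sided. Changes are log2 differences of group means, first group minus second, with their standard error. That error and its p-value come from the fit of all arrays, so they take in spread within groups outside the comparison. A ratio given as "at least" sets the bright group's mean against the dim group's mean of, per array, the higher of the feature's own value and the lowest signal among probes well above background. It is given only where a feature was dim on every array of a group, and 1 probe above background is enough not to be dim. Fitted sizes against other low groups are uncertain, as for flv4, flv2 and ndhD5 in the wild type at high CO2 and sll1594 in the mutant.

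Gene lists were tested with camera, among features with a value on every array, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Lists of mRNAs were set against the other mRNAs, and the regulatory RNAs, of which 3 were tested, against all other features. They were NdhR-linked carbon uptake, the BCT1 operon, carboxysome and Rubisco, constitutive CO2 uptake and NDH-1 core, Calvin-Benson cycle, photorespiration, NtcA-activated nitrogen genes, photosystem I, photosystem II, phycobilisome, chlorophyll, heme and bilin synthesis, ATP synthase, cytochrome b6f, flavodiiron proteins, ribosomal proteins, sugar catabolism, TCA cycle, heat shock, high-light inducible genes, iron, phosphate, hydrogenase, sigma factors, type IV pili, plasmid pSYSA and regulatory RNAs. Lists for plasmids pSYSM, pSYSX and pSYSG were not measured. The lists, the tests, the threshold and the rule for named genes were fixed before the data were examined. The files give locus tags, so gene symbols are background knowledge set down with the lists. The reference table of 3347 genes matched 0 of the 3364 tags, and no positions are given.

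The rule named slr1594 first, then a fixed panel of carbon, nitrogen and photosynthesis genes, then per comparison the 10 mRNAs with the largest rise and the 10 with the largest fall (5 and 5 for 24 h against 3 h and for differing responses), 3 antisense or non-coding features each way, and up to 4 members of each called list. For the largest rises and falls the groups' arrays had to be apart. This condition was not applied to differing responses, to the panel or to members of called lists. A gene that 2 parts of the rule name counts under both.

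Slides and scan days were read from the files: 5 slides and 4 scan days. Values within a slide used the arrays of the groups that share it, and slide or scan day also entered the fit as a block. Overlaps of calls were set beside the number expected for independent calls and beside 50 simulations. In these no group differed and nothing but shared control arrays linked the comparisons.

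Other settings tried were quantile, cyclic loess and median scaling, normexp background correction with an offset of 50, the submitters' processed values, no filter on dim probes and a stricter one that asks for every array, outlier-marked spots kept, the median over probes, no trend in the prior variance, slide as a fixed or random block, scan day or replicate number as a block, the compared groups alone, a change of at least 1 on the log2 scale, and leaving out each array in turn. Array weights and the removal of both 3 h arrays numbered 2 were added after the data were seen. The pipeline was tested on simulated data for the mutant against the wild type at high CO2, with 200 changed features in each of 5 simulations of 8238 features. It recovered 51.3% of changes of 1, 87.8% of changes of 2 and 97.0% of changes of 4 on the log2 scale, and 4.15% of 820 calls were false. The simulated noise was normal and independent, with 1 SD per feature for all groups. These rates therefore do not cover unequal spread between groups or links between features and slides. The tools were R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15 and matplotlib 3.10.9.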

Results

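The arrays measured RNA from the cyanobacterium Synechocystis sp. PCC6803 in a glucose-tolerant wild type and in the ΔndhR mutant, in which the labels give slr1594 as interrupted by the kanamycin resistance cassette aphII. NdhR is a LysR-type regulator known as a repressor of inorganic carbon uptake genes. Cultures grown at 5% CO2 were washed, resuspended in fresh medium, kept for 1 h at 5% CO2 (high CO2) and then moved to air with 0.035% CO2 (low CO2) for 3 or 24 h. The 13 arrays fell into 6 groups, with 2 arrays each for the wild type at high CO2, at 3 h and at 24 h, 2 each for the mutant at high CO2 and at 3 h, and 3 for the mutant at 24 h. No culture was kept at high CO2 for 3 or 24 h, so the fall in CO2 and the time in fresh medium changed together in every low-CO2 comparison. The labels give 50 µg/ml kanamycin for the mutant cultures and none for the wild type. Strain and kanamycin therefore differed together in every comparison that sets the strains against each other.

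Each array carried 20363 probes for 8830 RNA features, of which 3364 were mRNAs, 1940 antisense transcripts and 615 non-coding RNAs, and 8308 features were tested. The 75th percentile of the signal lay between 4157 and 7313 brightness units per array, 76.2% to 90.1% of spots were well above background, and 0 spots were saturated. The number of arrays limits the precision. Across features, which are not independent replicates, the replicates correlated at r = 0.987 in the wild type at high CO2, 0.947 at 3 h and 0.988 at 24 h, and at 0.995 in the mutant at high CO2, 0.912 at 3 h and 0.990 to 0.993 at 24 h. The first principal component held 63.0% of the variance and the second 14.3%. The arrays came from 5 slides, so values within a slide or with slide as a block stand beside the results. Of 93 list tests past the threshold with a preset correlation between genes, 6 held with an estimated correlation, all for the NdhR-linked list: in the wild type at 3 h, in the mutant against the wild type at each condition and in both tests of a differing response.

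The gene that the labels give as interrupted came first. The slr1594 mRNA feature, measured with 4 probes, lay between −4.05 and −1.63 on the 6 wild-type arrays and between −3.10 and −1.66 on the 7 mutant arrays, as log2 signal relative to each array's 75th percentile. Mutant minus wild type was 1.73 ± 0.47 at high CO2 (SE, n = 2 and 2; adjusted p = 0.375), −0.32 at 3 h and −0.10 at 24 h, none past the threshold. The files do not place the probes relative to the insertion, and a probe outside an interrupted part reports nothing on it, so these values neither show nor exclude the disruption. The feature sll1594, which carries the same number in the other tag series, lay between −2.45 and 0.08 in the wild type and between −5.31 and −4.38 in the mutant, below every wild-type array. From background knowledge sll1594 is the tag of ndhR itself, and the files do not settle whether the label means that gene.

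**Figure D1:**
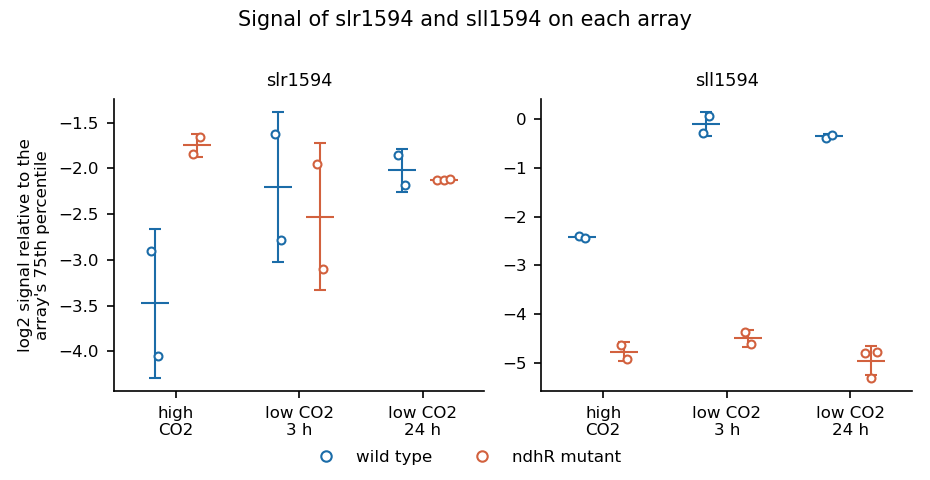
Log2 signal relative to each array's 75th percentile (vertical axis) of slr1594 and sll1594 in the 6 groups, with points for arrays and bars for the mean ± SD. For slr1594 the wild type spans −4.05 to −1.63 and the mutant −3.10 to −1.66, while all 7 mutant arrays of sll1594 lie at or below −4.38.

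The wild type at 3 h of low CO2 against high CO2 gave the parent strain's early response to low CO2 and time in fresh medium together. Genes of the high-affinity carbon uptake systems and flavodiiron genes were among those that rose most. The ndhF3, ndhD3 and cupA genes (sll1732, sll1733, sll1734) encode parts of the inducible CO2 uptake complex and rose by 6.67 ± 0.50, 6.14 ± 0.48 and 5.20 ± 0.50 (log2 ± SE, n = 2 and 2; adjusted p = 3.21e-05, 4.09e-05 and 8.35e-05). The bicarbonate transporter gene sbtA (slr1512) rose by 5.39 ± 0.76, and cmpB (slr0041), of the BCT1 bicarbonate transporter, by 9.55 ± 2.22, at least 164-fold against a dim group (adjusted p = 0.00067 and 0.00785). The flavodiiron genes flv4 and flv2 (sll0217, sll0219), whose proteins protect photosystem II, rose by 9.09 ± 2.06 and 8.58 ± 1.81. The errors of cmpB, sbtA, flv4 and flv2 come from the fit of all arrays, so they take in the mutant 3 h arrays. Those arrays part for flv4 at 4.35 and −4.72, while the wild-type 3 h arrays stood at 4.57 and 3.52. The errors and adjusted p therefore do not describe the spread of the compared groups alone. Genes for ribosomal proteins, nitrogen uptake and chaperones fell, among them rplE (sll1808) by 3.27 and the nitrate transporter gene nrtA (sll1450) by 3.49 (adjusted p = 0.000144 and 0.00434).

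Of 8308 features, 1697 were higher and 1654 lower at 3 h, 643 and 854 of them mRNAs. Of 18 measured NdhR-linked genes 16 were higher, or 17 adjusted over the list alone, with a median of 1.69 (camera adjusted p = 3.93e-09, or 0.0337 with an estimated correlation). All 6 genes of the BCT1 operon were higher by either count, with a median of 8.02 (adjusted p = 0.00424, or 0.43 with an estimated correlation). Of 19 genes for constitutive CO2 uptake and the NDH-1 core, 12 were higher and 1 lower, or 13 and 3 adjusted over the list alone, including ndhC (slr1279) at 2.35 ± 0.46 and ndhA (sll0519) at 2.17 ± 0.44 (list median 1.19, adjusted p = 0.00342, or 0.43 with an estimated correlation). In the same list ndhD4 (sll0027), of constitutive CO2 uptake, stood at −0.87, so the list median does not describe every member. Of 12 carboxysome and Rubisco genes 7 were lower, or 9 adjusted over the list alone, with ccmK3 (slr1838) of the shell at −1.02 ± 0.19 (median −0.68, adjusted p = 0.0314, or 0.34 with an estimated correlation); without the high-CO2 replicate 1 the list's adjusted p was 0.0654. The uncalled bicarbonate transporter gene bicA (sll0834) stood at −0.22 and rbcL (slr0009), of Rubisco, at 0.15. The 5 flavodiiron genes had 3 higher, or 4 higher and 1 lower adjusted over the list alone, and the list test gave an adjusted p of 0.0932 at a median of 8.58.

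Many genes for carbon fixation, photosystem II and ATP synthase were lower at 3 h. Of 12 Calvin-Benson genes 8 were lower by either count, with rpiA (slr0194) at −2.68 ± 0.39 (median −0.96, adjusted p = 0.00342, or 0.34 with an estimated correlation). Photosystem II had 17 lower and 1 higher of 24, or 19 and 3 adjusted over the list alone, with psbE (ssr3451) at −1.82 ± 0.33 (median −1.04, adjusted p = 0.00128, or 0.43 with an estimated correlation). All 10 ATP synthase genes were lower by either count, with atpC (sll1327) at −1.91 ± 0.40 (median −1.61, adjusted p = 0.00169, or 0.45 with an estimated correlation). Of 17 phycobilisome genes 4 were lower and 1 higher by either count (median −1.95, adjusted p = 0.0331, or 0.507 with an estimated correlation). That call was lost without the high-CO2 replicate 1 (median −1.93, adjusted p = 0.0654), without the 3 h replicate 1 (−0.97, 0.147) and with scan day as a block (adjusted p = 0.0754). Of 16 genes for chlorophyll, heme and bilin synthesis 8 were lower by either count, with hemL (sll0017) at −1.29 ± 0.26 (median −0.76, adjusted p = 0.0151, or 0.475 with an estimated correlation), and without the 3 h replicate 1 the adjusted p was 0.0718 and without replicate 2 the median was −1.26. Photosystem I had 0 of 12 genes past the limma threshold (median −0.57, camera adjusted p = 0.523). The cytochrome b6f list had 4 lower and 1 higher of 10, or 5 and 1 adjusted over the list alone (adjusted p = 0.106), and photorespiration 6 lower and 2 higher of 11 by either count (adjusted p = 0.094).

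All 23 ribosomal protein genes of the main cluster were lower by either count, with a median of −3.01 (adjusted p = 1.04e-14, or 0.34 with an estimated correlation). Nitrogen genes activated by NtcA, the global nitrogen regulator, had 13 lower and 1 higher of 18, or 14 and 1 adjusted over the list alone (median −2.60, adjusted p = 0.00424, or 0.45 with an estimated correlation). Of 10 heat shock genes 7 were lower by either count, including groEL2 (sll0416) at −3.45 ± 0.52 and dnaK2 (sll0170) at −2.80 ± 0.56 (median −1.99, adjusted p = 0.00629, or 0.34 with an estimated correlation). Sugar catabolism had 8 higher and 2 lower of 16, or 8 and 4 adjusted over the list alone, with zwf (slr1843), the first enzyme of the oxidative pentose phosphate pathway, at 1.85 ± 0.17 (median 0.46, adjusted p = 0.0331, or 0.34 with an estimated correlation). All 9 type IV pilus genes (median 1.10, adjusted p = 0.000386, or 0.34 with an estimated correlation) and 4 of 5 hydrogenase genes (median 1.36, adjusted p = 0.0116, or 0.43 with an estimated correlation) were higher by either count; without the 3 h replicate 1 the pilus median was 0.67. On plasmid pSYSA 22 of 95 genes were higher and 2 lower, or 14 and 1 adjusted over the list alone (median 0.36, adjusted p = 0.000405, or 0.34 with an estimated correlation). Of 12 phosphate limitation genes 5 were higher by either count, with pstA2 (slr1249) at 1.83 ± 0.26 (median 1.27, adjusted p = 0.00365, or 0.45 with an estimated correlation). The median was −0.05 without the high-CO2 replicate 1 (adjusted p = 0.287) and 0.13 within slide 2, and slide as a block gave an adjusted p of 0.0704.

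Genes of 5 further lists did not pass the list test at 3 h. The iron list had 4 lower of 8 by either count (median −0.56, adjusted p = 0.139), and the TCA cycle list 3 higher and 5 lower of 14, or 4 and 6 adjusted over the list alone, at a median of −0.13 and an adjusted p of 0.995, with the test's direction upward. Of 9 sigma factor genes 1 was higher by either count (median 0.27, adjusted p = 0.106). The 8 high-light inducible genes (median 0.44, adjusted p = 0.523) and the 3 regulatory RNAs tested (median −0.30, adjusted p = 0.311) had 0 members past the limma threshold. Antisense transcripts were more often higher, 432 against 132. The antisense feature sll0217-as2-0-x, named for the flv4 gene, fell by 4.49 on the log2 scale. The non-coding RNA NC-1413 rose by 6.40 ± 0.44. Within slide 2, which held 1 array of each group, the medians of the 17 called lists ran from −3.05 to 8.45, and with slide as a block 3069 features were called. Without the high-CO2 replicate 2, 2081 features were called.

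**Figure D2:**
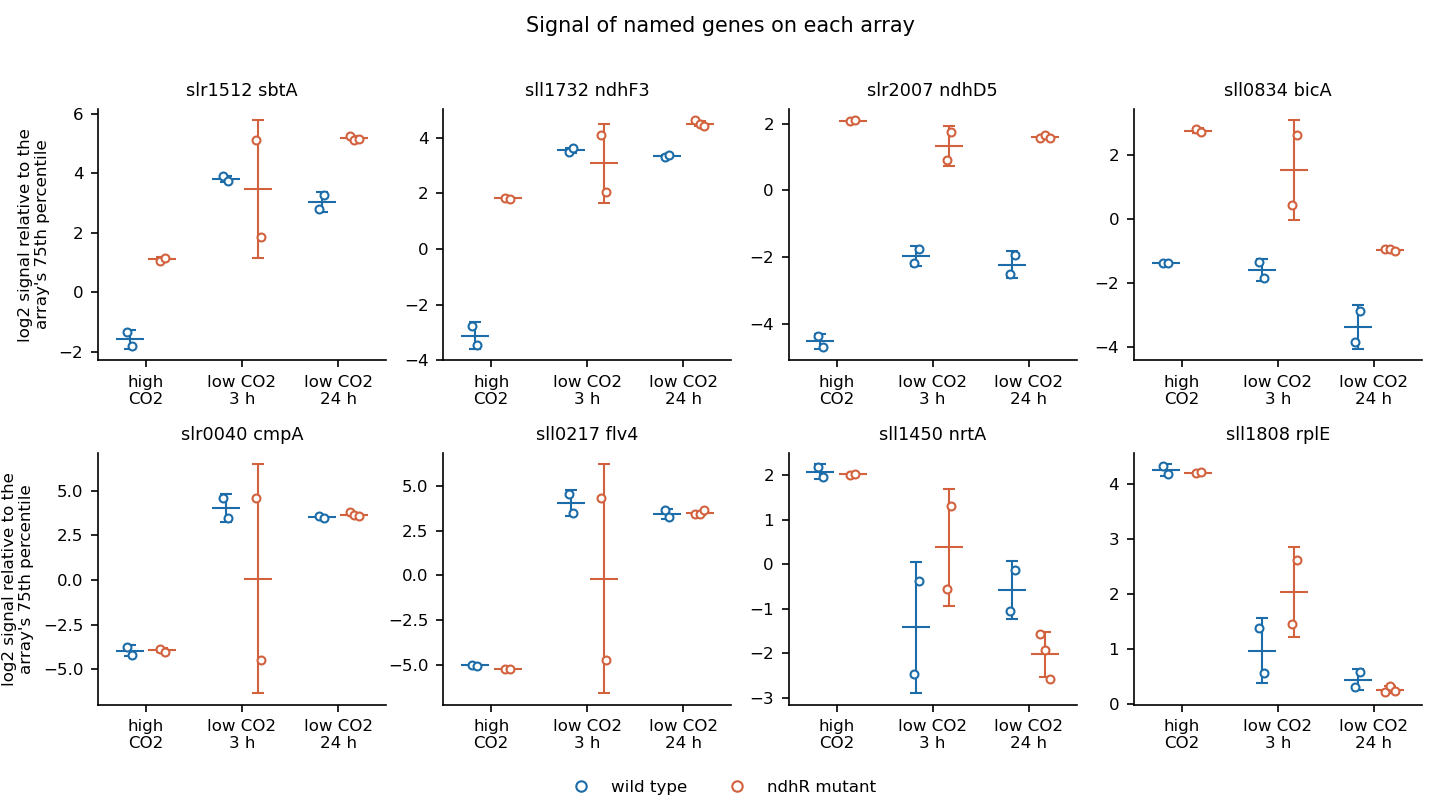
Log2 signal relative to each array's 75th percentile (vertical axis) of 8 genes (sbtA, ndhF3, ndhD5, bicA, cmpA, flv4, nrtA and rplE) in the 6 groups, with points for arrays and bars for the mean ± SD. In the mutant at 3 h the arrays part for cmpA (4.59 and −4.45) and flv4 (4.35 and −4.72), while ndhF3 in the mutant at high CO2 averages 1.81.

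The wild type at 24 h against high CO2 showed the longer response. Carbon uptake genes were again far above their high-CO2 level: ndhF3 by 6.46 ± 0.50, sbtA by 4.61 ± 0.76, flv4 by 8.51 ± 2.06 and cmpC (slr0043), of the BCT1 transporter, by 7.42 ± 1.72 (n = 2 and 2; adjusted p = 2.26e-05, 0.00112, 0.00814 and 0.00651). Ribosomal protein and ATP synthase genes lay below it, with rplE at −3.80 ± 0.35 and atpC at −2.75 ± 0.40. All these errors come from the fit of all arrays and also take in spread within groups outside this comparison. Genes for the sigma factors sigF (slr1564), linked to motility, and sigG (slr1545) rose by 1.64 ± 0.18 and 1.46 ± 0.26. The non-coding RNA NC-1136 rose by 7.80 ± 0.86 and NC-240 fell by 6.72 (adjusted p = 0.000124 and 0.000264).

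In all, 1965 features were higher and 1828 lower at 24 h, 665 and 996 of them mRNAs. The NdhR-linked list had 16 higher and 1 lower by either count (median 1.43, adjusted p = 2.82e-07, or 0.0651 with an estimated correlation), and the BCT1 operon 5 of 6 higher by either count (median 7.45, adjusted p = 0.0111, or 0.55 with an estimated correlation). The NDH-1 core list had 12 higher and 1 lower, or 12 and 4 adjusted over the list alone, with ndhA at 2.15 ± 0.44 (median 0.91, adjusted p = 0.00789, or 0.55 with an estimated correlation). Its member ndhD4 stood at −0.85. All 10 ATP synthase genes (median −2.23, adjusted p = 0.000423, or 0.55 with an estimated correlation) and all 23 ribosomal protein genes (median −3.58, adjusted p = 7.5e-14, or 0.444 with an estimated correlation) were lower by either count. Of the Calvin-Benson genes 9 were lower by either count, with tpiA (slr0783) at −2.36 ± 0.37 (median −0.91, adjusted p = 0.00963, or 0.403 with an estimated correlation). NtcA-activated genes had 13 lower by either count (median −2.06, adjusted p = 0.0135, or 0.608 with an estimated correlation). Of 9 sigma factor genes 6 were higher by either count (median 0.80, adjusted p = 0.0113, or 0.55 with an estimated correlation). Type IV pilus genes had 7 higher, or 8 adjusted over the list alone, with pilA1 (sll1694), the major pilin, at 1.96 ± 0.43 (median 1.16, adjusted p = 0.000305, or 0.403 with an estimated correlation).

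The 24 h calls for pSYSA (23 higher and 7 lower, or 20 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.00789, or 0.55 with an estimated correlation) and hydrogenase (4 higher by either count; median 0.88, adjusted p = 0.0457, or 0.55 with an estimated correlation) depended on single arrays. The first had an adjusted p of 0.0776 and a median of 0.08 without the high-CO2 replicate 2. The second had 0.0731 without the high-CO2 replicate 1, 0.0679 without the 24 h replicate 2 and 0.0527 without either wild-type 3 h replicate. The bicA gene fell by 1.99 (adjusted p = 0.0166), a call lost without the high-CO2 replicate 1 (adjusted p = 0.066), the high-CO2 replicate 2 (0.067) or the 24 h replicate 1 (0.13). The slr1594 feature rose by 1.45 ± 0.47 (adjusted p = 0.029); its change was 0.88 without the high-CO2 replicate 2 (adjusted p = 0.22), 1.29 without the 24 h replicate 1 (0.14) and 1.62 without the 24 h replicate 2 (0.065), and slide as a block gave an adjusted p of 0.0909. Within slide 1 the medians of the NdhR-linked, BCT1 and ribosomal lists were 1.30, 7.45 and −3.75. The count was 4136 with slide as a block and 2251 without the 24 h replicate 1.

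Between 3 and 24 h in the wild type a smaller set of genes moved, and the carbon uptake genes sbtA, ndhF3 and flv4 stood at −0.78, −0.21 and −0.59 without passing the test (adjusted p = 0.513, 0.81 and 0.873). The genes slr1634 and sll1158 rose by 2.33 ± 0.18 and 2.29 ± 0.28 (n = 2 and 2; adjusted p = 0.000432 and 0.00173), and slr1667 by 3.08 ± 0.27 (adjusted p = 0.000528, and 0.0555 with scan day as a block). The sll0723 and slr0554 genes fell by 2.66 and by 2.23 (adjusted p = 0.00199 and 0.00139, and 0.061 for both with scan day as a block). In all 750 features were higher and 657 lower. No slide held both groups. The count was 233 without the 24 h replicate 1, 665 without the 24 h replicate 2, 560 with slide as a block, 21 with scan day as a block and 0 in a limma fit of the compared groups alone.

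The list tests between 3 and 24 h passed for 3 lists. Photosystem II had 2 genes higher by either count (median 0.33, adjusted p = 0.0286, or 0.889 with an estimated correlation), and without the 3 h replicate 1 the adjusted p was 0.304. Photosystem I had 0 genes past the limma threshold at a median of 0.92 (camera adjusted p = 0.0468, or 0.909 with an estimated correlation). Its adjusted p was 0.373 without the 3 h replicate 1, 0.114 without the 24 h replicate 2, 0.0581 and 0.0583 without the high-CO2 replicates 1 and 2, and 0.051 and 0.0545 without the mutant 24 h replicates 2 and 3. Phosphate limitation had 4 genes lower by either count (median −1.20, adjusted p = 0.0285, or 0.889 with an estimated correlation). With slide as a block none of the 3 held (adjusted p = 0.165, 0.304 and 0.82).

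The mutant at 3 h against its high-CO2 level asked for the early response without NdhR. Phosphate limitation genes rose, with pstS2 (slr1247), a phosphate-binding protein gene, at 3.84 ± 0.55 (n = 2 and 2; adjusted p = 0.0018; with slide as a block 3.35, adjusted p = 0.0646). The pentose phosphate pathway genes zwf and gnd (sll0329) rose by 1.32 ± 0.17 and 1.14 ± 0.20, and rplE, sll1863 and sll1823 fell by 2.17, by 3.66 and by 2.96; with scan day as a block the calls of zwf, gnd and rplE were lost (adjusted p = 0.0594, 0.073 and 0.074). The carbon uptake genes cmpA and sbtA did not pass (adjusted p = 0.197 and 0.051), and their 3 h arrays differed: cmpA (slr0040) stood at 4.59 in replicate 1 and −4.45 in replicate 2, against a high-CO2 mean of −3.93 ± 0.12 (SD), and sbtA at 5.11 and 1.84, against 1.10 ± 0.08. The BCT1 operon list lay 8.51 above the high-CO2 mean in replicate 1 and 0.37 in replicate 2, and the ribosomal list at −2.55 and −1.59. The phosphate list lay at 2.51 and 2.71, so the arrays did not part for every group.

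The mutant's 3 h response counted 864 features higher and 935 lower, 312 and 528 of them mRNAs. The count was 3112 without the 3 h replicate 2, 1188 without the 3 h replicate 1, 594 and 619 without the high-CO2 replicates 1 and 2, 765 with slide as a block, 156 with scan day as a block and 28 in a fit of the compared groups alone. Phosphate limitation had 11 of 12 genes higher, or 12 adjusted over the list alone (median 2.53, adjusted p = 1.76e-07, or 0.444 with an estimated correlation). All 23 ribosomal protein genes were lower by either count (median −2.02, adjusted p = 9.24e-15, or 0.444 with an estimated correlation). So were 4 Calvin-Benson genes, or 6 adjusted over the list alone (median −0.53, adjusted p = 0.0129, or 0.444 with an estimated correlation), and 5 heat shock genes, or 8 adjusted over the list alone (median −1.73, adjusted p = 0.0135, or 0.502 with an estimated correlation). Without the 3 h replicate 2 the Calvin-Benson median was −0.83, with 8 genes lower, and without replicate 1 the heat shock median was −1.01. Type IV pili had 8 genes higher, or 9 adjusted over the list alone (median 0.88, adjusted p = 1.78e-05, or 0.444 with an estimated correlation). On pSYSA 11 were higher and 1 lower over all genes, and 0 by limma adjusted over the list alone (median 0.21, adjusted p = 0.000312, or 0.444 with an estimated correlation).

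The remaining mutant calls at 3 h rested on 1 of its 3 h arrays. Without replicate 1 the BCT1 operon (0 genes, or 5 higher adjusted over the list alone; median 4.28, adjusted p = 0.02, or 0.598 with an estimated correlation) had a median of 0.37 and an adjusted p of 0.304. The NDH-1 core list (2 higher by either count; median 0.78, adjusted p = 0.00948, or 0.598 with an estimated correlation) then had 0.10 and 0.214. ATP synthase (1 lower, or 6 adjusted over the list alone; median −0.96, adjusted p = 0.02, or 0.649 with an estimated correlation) had −0.41 and 0.304, and hydrogenase (3 higher, or 5 adjusted over the list alone; median 1.05, adjusted p = 0.0129, or 0.502 with an estimated correlation) had 0.51 and 0.054. Without replicate 2 sugar catabolism (7 higher and 2 lower, or 9 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.0229, or 0.444 with an estimated correlation) had an adjusted p of 0.104. The ATP synthase call was also lost with slide as a block (adjusted p = 0.0774). The NdhR-linked list had 8 genes lower, or 3 higher and 9 lower adjusted over the list alone, at a median of −0.76 and a camera adjusted p of 0.296. Without replicate 2 the changes were 8.52 for cmpA and 2.27 for ndhF3, both past the threshold (adjusted p = 1.24e-06 and 0.000187). No slide held both groups.

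At 24 h the mutant against its high-CO2 level showed the longer response without NdhR, with n = 3 and 2. Genes of the BCT1 transporter and flavodiiron genes were among those with the largest rises: cmpB by 9.29 ± 2.02, at least 137-fold, and flv4 by 8.75 ± 1.88, at least 208-fold (adjusted p = 0.00329 and 0.00311). The sbtA gene rose by 4.08 ± 0.69 and ndhF3 by 2.69 ± 0.45 (adjusted p = 0.000854 and 0.000811), while bicA fell by 3.70 (adjusted p = 0.000275). The errors of cmpB, flv4, sbtA and ndhF3 take in the mutant 3 h arrays, which part for these genes. Nitrogen genes fell, with glnA (slr1756), encoding glutamine synthetase, at −4.24 ± 0.85, and ssl1911, encoding an inhibitor of that enzyme, rose by 4.24 ± 0.94. The genes slr1214 and slr0376 rose by 5.31 ± 0.41 and 4.79 ± 0.49, and cpcG2 (sll1471), a phycobilisome linker gene, fell at least 16.7-fold.

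A total of 2532 features were higher and 2325 lower, 784 and 1254 of them mRNAs. All 6 BCT1 genes were higher by either count (median 7.61, adjusted p = 0.00829, or 0.629 with an estimated correlation), and the NDH-1 core list had 13 higher and 3 lower by either count, with ndhA at 2.05 ± 0.40 (median 1.03, adjusted p = 0.00447, or 0.629 with an estimated correlation). In the latter list ndhD4 stood at −0.84. Lower by either count were 10 Calvin-Benson genes, with rpiA at −3.70 ± 0.36 (median −1.11, adjusted p = 0.00742, or 0.629 with an estimated correlation), and 14 NtcA-activated genes (median −3.15, adjusted p = 0.00711, or 0.685 with an estimated correlation). The same held for all 10 ATP synthase genes (median −2.78, adjusted p = 0.000784, or 0.629 with an estimated correlation) and all 23 ribosomal protein genes (median −3.46, adjusted p = 3.15e-11, or 0.629 with an estimated correlation). Sigma factors had 7 higher, or 8 adjusted over the list alone, with sigI (sll0687) at 1.71 ± 0.20 (median 0.96, adjusted p = 0.00447, or 0.629 with an estimated correlation). Type IV pili had 5 higher, or 7 adjusted over the list alone (median 0.70, adjusted p = 0.00387, or 0.629 with an estimated correlation), and pSYSA 25 higher and 11 lower, or 24 and 11 adjusted over the list alone (median 0.22, adjusted p = 0.00982, or 0.629 with an estimated correlation). The NdhR-linked list went both ways, with 7 higher and 8 lower, or 7 and 9 adjusted over the list alone; its median was −0.56, its mean 0.39 and its camera adjusted p 0.766.

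A pair of the mutant's 24 h list calls depended on single arrays. Hydrogenase had 4 genes higher by either count (median 1.17, adjusted p = 0.0256, or 0.629 with an estimated correlation), with an adjusted p of 0.0519 without the high-CO2 replicate 2. Phosphate limitation had 5 genes higher over all genes and 0 by limma adjusted over the list alone (median 0.87, adjusted p = 0.0364, or 0.786 with an estimated correlation). Its adjusted p was 0.0539 without the high-CO2 replicate 2, 0.0573 and 0.0571 without the 3 h replicates 1 and 2, and 0.156 with slide as a block. Within slide 1 the change of ndhF3 was 2.79, of sbtA 4.21 and of bicA −3.73, and with slide as a block 4404 features were called.

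From 3 to 24 h in the mutant (n = 3 and 2), slr1214, slr0376 and sll1158 rose by 4.63 ± 0.41, 3.81 ± 0.49 and 3.31 ± 0.26, and cpcG2 fell at least 19.2-fold (adjusted p = 0.00026, 0.000733, 0.000128 and 0.00229). The phosphate gene pstS2 fell by 3.47, and atpC and rplE fell by 2.17 and by 1.77 (adjusted p = 0.00114, 0.00198 and 0.00273); without the 3 h replicate 2 rplE stood at −1.19, atpC at −1.55 and cpcG2 at least 6.37-fold lower, all past the threshold. The sigF gene rose by 1.51 ± 0.16 and the non-coding RNA NC-1136 by 6.28 ± 0.79. The bicA gene fell by 2.48 (adjusted p = 0.00526), and by 1.38 without the 3 h replicate 2. In all 1490 features were higher and 1591 lower, and 1753 were called without the 3 h replicate 2. With slide as a block 3948 were called.

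Among the lists from 3 to 24 h in the mutant, all 10 ATP synthase genes (median −1.92, adjusted p = 0.00026, or 0.812 with an estimated correlation) and all 23 ribosomal protein genes (median −1.45, adjusted p = 2.64e-08, or 0.812 with an estimated correlation) were lower by either count; without the 3 h replicate 2 the ribosomal median was −0.96, with 22 genes lower. Phosphate limitation had 7 lower by either count (median −1.51, adjusted p = 0.0131, or 0.812 with an estimated correlation; adjusted p = 0.158 with slide as a block). NdhR-linked genes had 3 higher and 1 lower by either count (median 0.30, adjusted p = 0.0254, or 0.812 with an estimated correlation); with slide as a block the adjusted p was 0.0899, and within slide 5 the median was −0.08. The sigma factor list had 5 higher and 2 lower, or 6 and 2 adjusted over the list alone (median 0.80, adjusted p = 0.0254, or 0.812 with an estimated correlation; adjusted p = 0.06 without the 3 h replicate 2). NtcA-activated genes had 8 lower, or 11 adjusted over the list alone (median −1.38, adjusted p = 0.0461, or 0.812 with an estimated correlation). Without the 3 h replicate 2 their median was −0.42 (adjusted p = 0.419), without the 24 h replicate 3 −1.29 (0.0657), and without either wild-type high-CO2 array or either wild-type 3 h array the adjusted p was 0.0539 or 0.0513.

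The mutant against the wild type at high CO2 asked which genes differ between the strains when carbon is plentiful. The slr2006 and ndhD5 (slr2007) genes, neighbours in tag order, were 8.18 ± 0.37 and 6.61 ± 0.28 higher in the mutant (n = 2 and 2; adjusted p = 1.22e-06 and 8.95e-07). The wild-type signal of ndhD5 lay near the background, so the size of its difference is uncertain. The CO2 uptake genes ndhF3 and ndhD3 were 4.93 ± 0.50 and 4.71 ± 0.48 higher (adjusted p = 0.000589 and 0.000627), and slr1592 4.50 ± 0.19; with the submitters' processed values ndhF3 and ndhD3 stood at 2.72 and 2.62 (adjusted p = 0.051 and 0.053). The slr0907 and sll1594 genes were lower, at −3.73 ± 0.16 and −2.36 ± 0.21 (adjusted p = 8.95e-07 and 0.000235). The mutant arrays of sll1594 stood at −4.64 and −4.92, near the background, so the size of its difference is uncertain. Of the 18 NdhR-linked genes 15 were higher, or 18 adjusted over the list alone, with a median of 3.65 (camera adjusted p = 6.28e-144, or 2.55e-06 with an estimated correlation), 3.69 within slide 1 and 3.42 with slide as a block (adjusted p = 8.69e-78).

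Few other genes differed at high CO2, with 34 features higher and 31 lower, 16 and 2 of them mRNAs. The BCT1 gene cmpA stood at 0.03 and flv4 at −0.19. The sbtA gene stood at 2.68 ± 0.76 without passing (adjusted p = 0.467). Its error takes in the mutant 3 h arrays, at 5.11 and 1.84, so the missing call does not show equal levels. The bicA gene was 4.12 ± 0.56 higher (adjusted p = 0.00497), a call lost without the wild-type replicate 2 (adjusted p = 0.057), the mutant replicate 1 (0.061) or the mutant replicate 2 (0.054), and with slide as a block (3.48, adjusted p = 0.17). The list tests also passed for phosphate limitation and pSYSA, each with 0 genes past the limma threshold by either count: the medians were −1.16 (camera adjusted p = 1.09e-08, or 0.881 with an estimated correlation) and −0.13 (adjusted p = 0.00103, or 0.966 with an estimated correlation). The first was −0.03 without the wild-type replicate 2 (adjusted p = 0.75) and 0.01 within slide 1, and the second −0.03 without the wild-type replicate 1 (adjusted p = 0.998). With slide as a block 30 of the features tested were called.

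At 3 h of low CO2 the mutant against the wild type gave a smaller gap for the NdhR-linked genes. The ndhD5 gene was 3.32 ± 0.28 higher, slr2006 3.91 ± 0.37, slr1592 3.75 ± 0.19 and slr1535 3.53 ± 0.27 (n = 2 and 2; adjusted p = 0.000318, 0.000645, 7.83e-06 and 0.000197). The slr0907 and sll1594 genes were lower, at −4.66 ± 0.16 and −4.40 ± 0.21. In the mutant sll1594 stood at −4.38 and −4.63, so low that the size of its difference is uncertain. Of 18 NdhR-linked genes 9 were higher, or 11 adjusted over the list alone (median 1.27, adjusted p = 1.96e-12, or 0.0131 with an estimated correlation), with 1.04 within slide 2 and 0.88 with slide as a block (adjusted p = 1.71e-08). The uncalled genes ndhF3, sbtA and cmpA stood at −0.48, −0.34 and −3.98 ± 2.06; without the mutant replicate 2 they stood at 0.54, 1.29 and 0.54, and sbtA then passed as higher (adjusted p = 0.0499). In all 28 features were higher and 31 lower, and 2 of the 59 rested on 1 array in a group. The count was 1573 without the mutant replicate 1, 26 with slide as a block and 0 in a limma fit of the compared groups alone.

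The other list calls at 3 h held few called genes, and all but 1 of those lists had 0 members past the limma threshold over all genes; the NDH-1 core list had 1 higher. Higher in the mutant and kept without each single array were photosystem II (median 0.50, camera adjusted p = 1.23e-06, or 0.32 with an estimated correlation), Calvin-Benson (0.34, adjusted p = 0.00156, or 0.308 with an estimated correlation) and ribosomal proteins (0.87, adjusted p = 1.92e-18, or 0.317 with an estimated correlation; 0.10 within slide 2, and 23 higher adjusted over the list alone). Without the mutant replicate 2 these medians fell to 0.20, 0.19 and 0.45. The pSYSA list was lower (−0.25, adjusted p = 6.71e-05, or 0.32 with an estimated correlation). A further 9 lists lost their calls without 1 array. Without the mutant replicate 2 BCT1 went from −3.55 (adjusted p = 0.00937, or 0.501 with an estimated correlation) to 0.47, the NDH-1 core from −0.51 (0.0324, or 0.501 with an estimated correlation) to 0.10, NtcA-activated genes from 0.83 (0.00188, or 0.501 with an estimated correlation) to −0.13 and photosystem I from 0.79 (0.00221, or 0.501 with an estimated correlation) to −0.30. Phycobilisome genes went from 1.15 (0.00105, or 0.501 with an estimated correlation) to −0.07, chlorophyll synthesis from 0.20 (0.02, or 0.501 with an estimated correlation) to −0.11 and ATP synthase from 0.59 (0.000583, or 0.501 with an estimated correlation) to 0.08. Without the wild-type replicate 1 these 7 lists stood at −3.02, −0.39, 0.15, 0.18, 0.34, 0.02 and 0.16, none past the threshold, and without the wild-type replicate 2 the NDH-1 core list had an adjusted p of 0.0642. The carboxysome list (0.24, adjusted p = 0.0226, or 0.32 with an estimated correlation) had an adjusted p of 0.219 without the wild-type replicate 1 and 0.157 without the mutant replicate 1. The cytochrome b6f list (0.35, adjusted p = 0.0226, or 0.308 with an estimated correlation) had 0.0957 and 0.0994 without the wild-type replicates 1 and 2 and 0.241 without the mutant replicate 1.

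At 24 h the NdhR-linked genes were again the group that set the strains apart (n = 3 and 2). The slr2006 and ndhD5 genes were 4.36 ± 0.34 and 3.84 ± 0.26 higher in the mutant (adjusted p = 0.00012 and 3.82e-05), slr1592 3.13 ± 0.18 and slr1262 2.70 ± 0.34. The sll1594 gene stood at −4.62 ± 0.19 (adjusted p = 1.9e-06), and slr0907 was at least 5.26-fold lower. The mutant arrays of sll1594 stood at −4.81, −5.31 and −4.78, near the background, so the size of its difference is uncertain. Of the 18 listed genes 10 were higher, or 18 adjusted over the list alone (median 1.95, adjusted p = 4.13e-33, or 0.000506 with an estimated correlation), with 2.11 within slide 1 and 1.90 with slide as a block (adjusted p = 4.25e-33). It was the single list past the threshold. The uncalled genes sbtA and ndhF3 stood at 2.14 ± 0.69 (adjusted p = 0.228) and 1.17 (adjusted p = 0.293). Their errors take in the mutant 3 h arrays, which part for both genes (sbtA 5.11 and 1.84, ndhF3 4.08 and 2.06). The missing calls therefore do not show equal levels at 24 h.

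In all 45 features were higher and 53 lower at 24 h. The count was 53 without the wild-type 24 h replicate 2, 64 without the mutant 24 h replicate 2, 171 without either mutant 3 h array and 26 with slide as a block. Across the 3 strain comparisons 37 features were called each time, 16 of them higher and 20 lower throughout and 1, slr1512-int1, in both directions; its 3 h value for the mutant rested on replicate 2, since replicate 1 held no usable value. The higher mRNAs were slr1592, slr2006 to slr2011, ssr3409 and ssr3410, and the lower ones sll1594 and slr0907. If sll1594 is ndhR itself, its lower signal may be the disruption and not a response to it.

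A group outside the rule for named genes, chosen after its values were seen, was the set of CRISPR spacer features, which stand for stored fragments of foreign DNA. Their names end in 0, 1 or 2, and the files do not say what this suffix means. Of 29 tested with suffix 2, 20 were lower in the mutant at high CO2, 17 at 3 h and 20 at 24 h, with medians of −2.15, −1.58 and −2.11. Spacer21-2-x, not well above background on any mutant array, was at least 9.48-fold, 6.09-fold and 7.60-fold lower. Of 43 tested with suffix 0, limma called 0 in each comparison, with medians of −0.35, −0.13 and −0.09, and of 23 with suffix 1 it called 3, 1 and 1 lower. Within slide 1 the suffix 2 medians were −2.50 at high CO2 and −2.57 at 24 h.

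**Figure D3:**
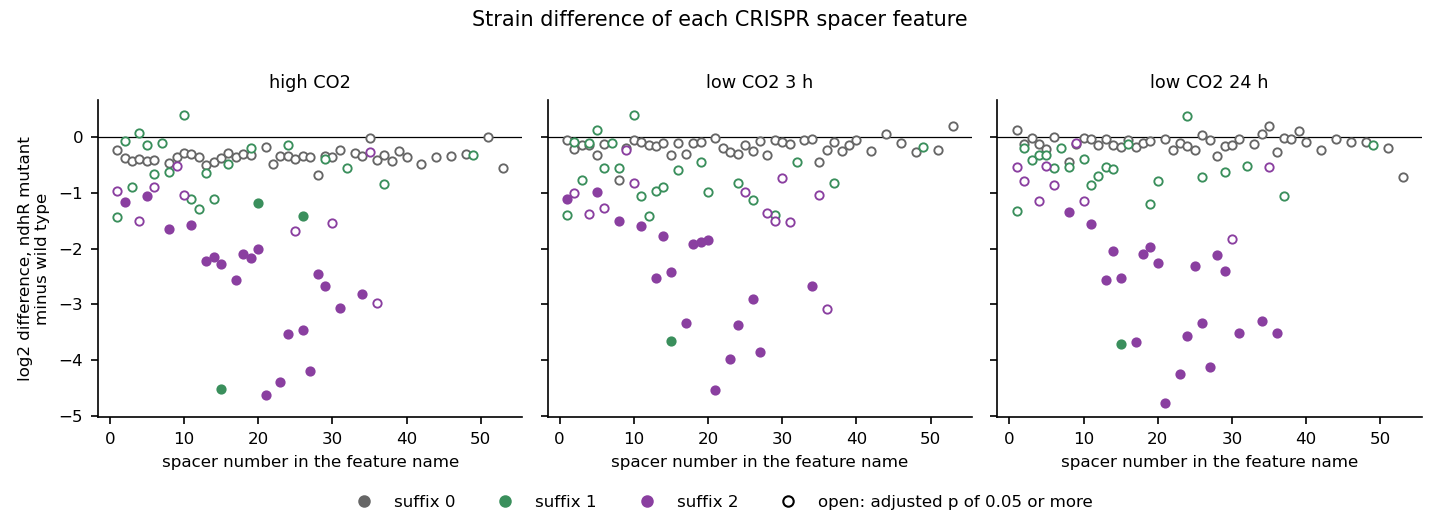
Mutant minus wild type as log2 change (vertical axis) against spacer number (horizontal axis) for the tested spacer features at high CO2, 3 h and 24 h, coloured by suffix and filled where called. The medians of suffix 2 are −2.15, −1.58 and −2.11 and those of suffix 0 −0.35, −0.13 and −0.09. For features not well above background in the mutant the plotted value is the fitted one and the true size is not known.

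The difference between the strains' low-CO2 responses was tested directly. The mutant's change minus the wild type's was positive for 2 called features and negative for 23 at 3 h, and for 4 and 11 at 24 h. The response of ndhF3 at 3 h was 5.41 ± 0.70 lower in the mutant (a difference of −5.41, adjusted p = 0.0114), with ndhD5 at −3.30 ± 0.40 and slr1535 at 3.18 ± 0.38 (adjusted p = 0.00828 for both). At 24 h ndhD5 stood at −2.77 ± 0.38 (adjusted p = 0.0233), slr2006 at −3.82 ± 0.50 and sll1594 at −2.26 ± 0.28, the last from a rise in the wild type while its mutant signal stayed low. The NdhR-linked list had a median difference of −2.16 at 3 h, with 11 genes lower, or 16 adjusted over the list alone (adjusted p = 2.06e-45, or 0.00017 with an estimated correlation), and of −1.65 at 24 h, with 4 lower, or 14 adjusted over the list alone (adjusted p = 4.67e-24, or 0.00148 with an estimated correlation). With slide as a block it was −2.28 and −1.46 (adjusted p = 5.32e-20 and 3.79e-32), and no slide held all the groups for 3 h. For sbtA and cmpA the differences were −3.02 and −4.01 at 3 h and −0.54 and 0.10 at 24 h, none past the threshold. Without the mutant 3 h replicate 2 the 3 h differences were −1.39 and 0.51, again not past it (adjusted p = 0.218 and 0.999). Among antisense transcripts limma called 0 differing responses at each time, with 57 and 70 at an unadjusted p below 0.05.

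Each of the 9 named genes with a differing response at 3 h and the 10 at 24 h lost its call without at least 1 array, and slide as a block left 3 and 0 features. The 3 h count was 7 without the wild-type high-CO2 replicate 2, 9 without the wild-type 3 h replicate 1, 5 without either mutant high-CO2 array and 323 without the mutant 3 h replicate 1. At 24 h it was 27 and 0 without the wild-type high-CO2 replicates 1 and 2, 0 without the wild-type 24 h replicate 2 or either mutant high-CO2 array, 40 without either mutant 3 h array, and 6, 3 and 0 without the mutant 24 h replicates 1, 2 and 3. A further 12 lists passed the test at 3 h, each with 0 genes past the limma threshold over all genes. Among them photosystem II (0.46) and ribosomal proteins (0.95) kept their calls without each single array (adjusted p = 0.419 and 0.411 with an estimated correlation), at 0.20 and 0.50 without the mutant 3 h replicate 2, and BCT1 (−3.43, adjusted p = 0.509 with an estimated correlation) went to 0.57 without the mutant 3 h replicate 2. The iron (0.41, adjusted p = 0.0171, or 0.562 with an estimated correlation) and phosphate lists (0.97, adjusted p = 0.00556, or 0.862 with an estimated correlation) passed at 24 h. Without the wild-type high-CO2 replicate 2 they stood at 0.28 (adjusted p = 0.0864) and −0.14 (0.324), without the wild-type 24 h replicate 1 at 0.32 (0.082) and 0.74 (0.0973). Without the mutant high-CO2 replicate 1 the iron list stood at 0.45 (0.0698).

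**Figure D4:**
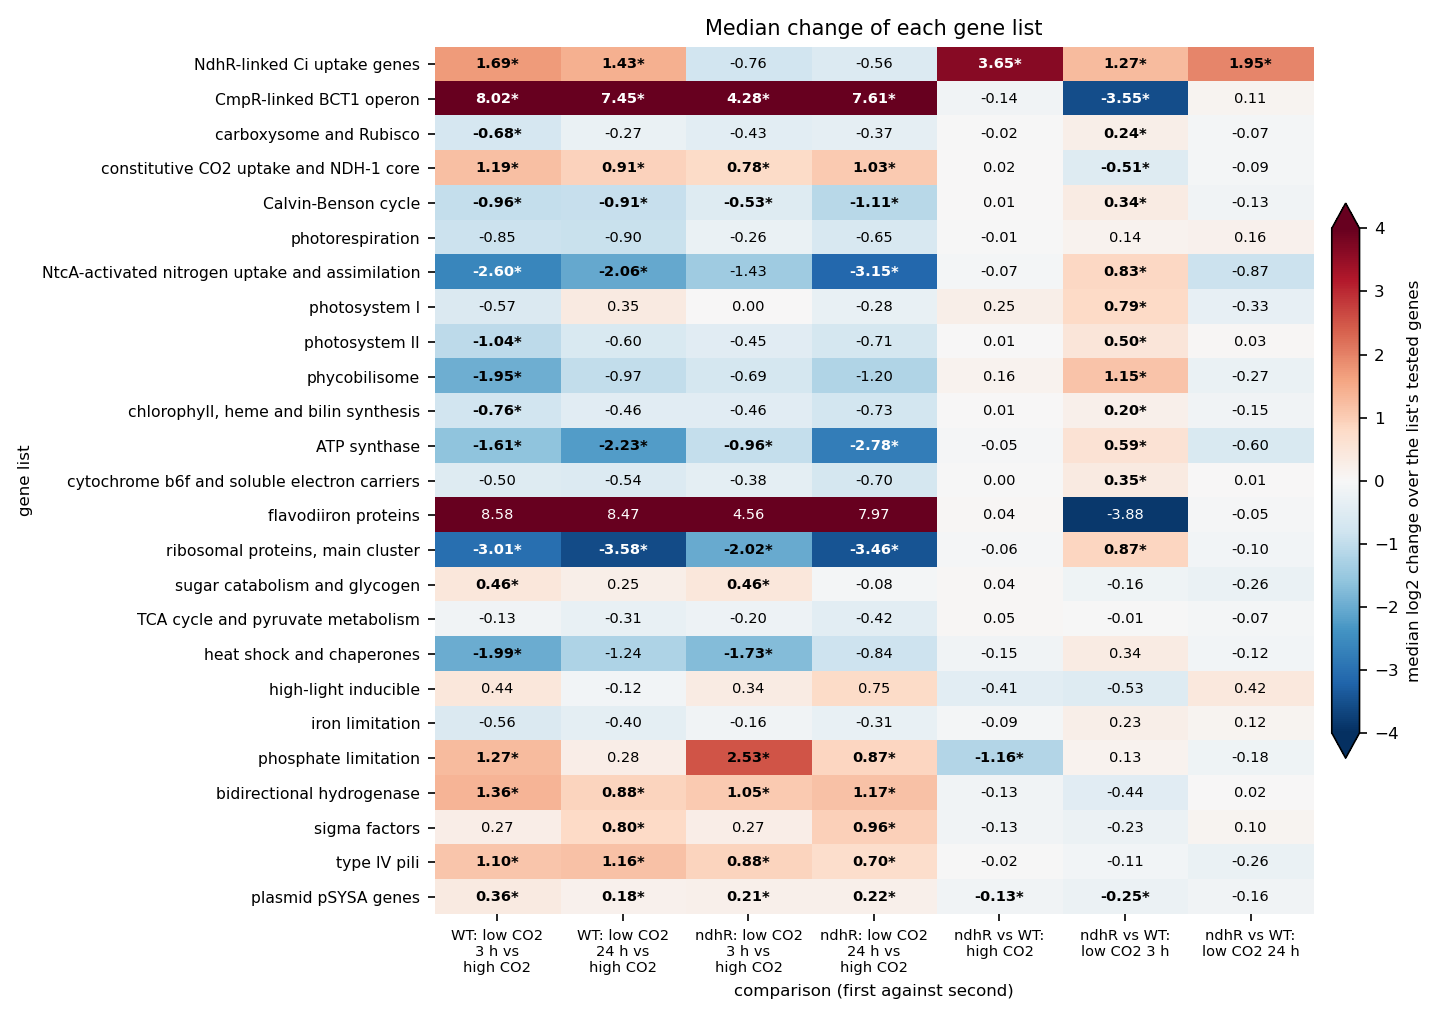
Median log2 change of each gene list (rows) in 7 comparisons (columns), as colour and printed value, with colours capped at 4 in either direction and bold starred values where the camera test passed with a preset correlation. NdhR-linked genes stand at 1.69 in the wild type at 3 h, 3.65 in the mutant against the wild type at high CO2 and −0.56 in the mutant at 24 h.

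The responses of the strains overlapped widely. At 3 h 788 features were higher in both strains, against 176 expected by chance, 877 lower, against 186, and 9 in opposite directions, and the changes correlated at r = 0.885 across features, which are not independent replicates. Without the mutant 3 h replicate 2 these counts were 1343, against 387 expected, 1428, against 372, and 18. At 24 h 1721 were higher in both, against 599 expected, 1690 lower, against 512, and 13 opposite, at r = 0.929. In the wild type 1073 features were higher at both times, against 401 expected, and 1225 lower, against 364, and in the mutant 577, against 263, and 815, against 262. The mutant counts without its 3 h replicate 2 were 1223, against 513, and 1379, against 476. These times share their high-CO2 arrays, which alone gave a simulated covariance of 0.0565 against 0.907 measured in the wild type and 0.0568 against 0.632 in the mutant. The simulations had 0 shared calls, but they held no group differences. Their 0 therefore does not show how much shared arrays add to the overlap of many calls. Each group has too few high-CO2 arrays to leave 2 per comparison, so they were not split, and part of the excess may come from them. Of the 34 features higher in the mutant at high CO2, 29 were among those that rose in the wild type at 3 h, against 6.94 expected, and 29 among those at 24 h, against 8.04; the wild-type high-CO2 arrays stand on both sides, with covariances of 0.0665 and 0.0458 against 0.0566 simulated.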

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

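Tests of explanations were chosen after the results were seen, except the test of slide differences for the lower low-CO2 change of NdhR-linked genes in the mutant at 24 h.

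A difference between the strains' low-CO2 responses marked each result here. It was called for 25 features at 3 h and 15 at 24 h. At 3 h the mutant's change minus the wild type's was −5.41 for ndhF3 (sll1732), −5.10 for ndhD3 (sll1733), −4.44 for cupA (sll1734), −3.30 for ndhD5 (slr2007), −4.27 for slr2006 and 3.18 for slr1535. The non-coding RNAs NC-1413, NC-1410 and NC-430 stood at −5.10, −5.08 and −2.62. At 24 h ndhD5 stood at −2.77, slr2006 at −3.82, ndhD6 (slr2009) at −2.27, slr2008 at −1.88 and sll1594 at −2.26. The last came from a rise in the wild type over a low, flat mutant signal. If sll1594 is ndhR itself, the disruption may have fixed that outcome. The slr1535 and cupB (slr1302) genes stood at 2.43 and 1.45, and NC-431, NC-430 and NC-445 at −4.61, −3.65 and −3.33. Each of these genes lost its call in a fit without 1 array, and with slide as a block. The NdhR-linked list stood at −2.16 at 3 h and −1.65 at 24 h and kept its call without each single array.

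Other lists differed at 3 h as well, by these medians: photosystem II 0.46, ribosomal proteins 0.95, Calvin-Benson 0.36, carboxysome 0.22, NtcA-activated genes 0.96, phycobilisome 0.98, chlorophyll synthesis 0.24, ATP synthase 0.65, iron 0.32, phosphate 1.48, the NDH-1 core −0.55 and BCT1 −3.43. With an estimated correlation none of these lists passed the camera test (adjusted p from 0.411 to 0.543). Photosystem II and ribosomal proteins kept their calls without each single array, at smaller medians of 0.20 and 0.50 without the mutant 3 h replicate 2. Without the mutant 3 h replicate 2 the calls were lost or turned for Calvin-Benson (0.19), carboxysome (0.12), NtcA-activated genes (−0.09), phycobilisome (−0.19), chlorophyll synthesis (−0.13), ATP synthase (0.14), iron (0.07), the NDH-1 core (0.07) and BCT1 (0.57). Without the wild-type 3 h replicate 1 these 9 lists stood at 0.27, 0.05, 0.25, 0.22, 0.06, 0.22, 0.17, −0.42 and −2.90, none past the threshold. The calls were also lost without the wild-type high-CO2 replicate 1 for Calvin-Benson (0.24), carboxysome (0.10), phycobilisome (0.96), the NDH-1 core (−0.47) and BCT1 (−3.28), and without replicate 2 for chlorophyll synthesis (0.11), iron (0.19) and phosphate (0.14). Calls were lost as well without the wild-type 3 h replicate 2 for the NDH-1 core (−0.60) and iron (0.39), and without the mutant 3 h replicate 1 for the carboxysome list (0.45). Without the mutant high-CO2 replicate 1 this held for the carboxysome (0.21) and chlorophyll lists (0.21), and without replicate 2 for the NDH-1 core (−0.43). At 24 h iron stood at 0.41 and phosphate at 0.97. Without the wild-type high-CO2 replicate 2 these were 0.28 and −0.14, and without the wild-type 24 h replicate 1 they were 0.32 and 0.74. Without the mutant high-CO2 replicate 1 iron was 0.45, not past the threshold.

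Carbon uptake genes were raised little or not at all in the mutant 3 h replicate 2, with the BCT1 operon 0.37 above the high-CO2 level against 8.51 in replicate 1. A high-CO2 culture carrying a 3 h label was argued against, because ribosomal protein genes lay at −1.59 from the high-CO2 mean, where the high-CO2 arrays differ by 0.0599. Slide 5 as the source was argued against, because the mutant 24 h arrays on it differed from the one on slide 1 by at most 0.194 in the BCT1 operon. A culture kept 3 h in fresh medium without the fall in CO2 stays open: its BCT1 share of replicate 1's movement was 0.0438 and its phosphate share 1.08, and the design holds no culture kept at high CO2 for 3 h. This explanation and a true difference between cultures cannot be told apart. The wild-type 3 h arrays also parted for some lists (phycobilisome −2.85 and −0.97 in replicates 1 and 2), though not for the BCT1 operon (8.55 and 7.43). Deviations from the 3 h group means correlated at 0.618 between the strains. With 2 arrays per group this value is the same for replicates 1 and 2. The replicate 1 arrays also share slide 2, so the correlation cannot be credited to replicate 2.

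The low-CO2 change of NdhR-linked genes at 24 h was lower in the mutant, with a median of −0.56 against 1.43 in the wild type. Slide differences were argued against, since within slide 1 the median difference of responses was −1.46. A ceiling of the signal was argued against for the 8 members that fell in the mutant at 24 h, and 0 spots were saturated. That fall does not bear on members that rose, such as ndhF3 (2.69). The loss of NdhR may account for the lower change. The list stood at 3.65 in the mutant against the wild type at high CO2 and at 1.95 at 24 h. These gaps make up the difference of responses, so they are no separate support. With 1 mutant line, grown with kanamycin, the loss of NdhR and other changes of that line cannot be told apart.

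Spacer features with the suffix 2 were lower in the mutant. Slide differences were argued against by a median of −2.50 at high CO2 within slide 1. Loss of spacers from the mutant's DNA as the whole cause was argued against by 11 of the 20 called lower at high CO2. These were well above background on every mutant array, for which 1 probe was enough. The argument holds only if that signal came from the spacers themselves, which was not tested. Another 6 of the 20, numbered 21, 23, 24, 26, 27 and 34, were dim on every mutant array and bright on every wild-type array. Numbers 28 and 29 were above background on every mutant array. The difference grew more negative with spacer number (rank correlation −0.57 at high CO2 and −0.33 at 3 h). Loss of some of the spacers stays open. The loss of NdhR (median −2.15), another change of the 1 mutant line and the kanamycin in its cultures cannot be told apart.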

How the results depend on the processing

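Array weights and the fits without both 3 h arrays numbered 2 were chosen after seeing the data. The cause was not tested for any change below, except that a higher bar lowers counts by construction. Of 622 called or panel values of named genes, slide as a fixed block left 495 unchanged in call and direction, scan day 474, array weights 539, cyclic loess 603, median scaling 611, quantile scaling 580 and the submitters' processed values 548. With the submitters' values, which keep the background, 422 of 423 called values kept their direction at a median size of 0.618 of the main one. Of 93 list calls an estimated correlation left 6, slide as a block 76, scan day 77 and median scaling 93. The median change of all features at 24 h, 0.0828 in the wild type and 0.0836 in the mutant, stood above 0.1 with quantile scaling (0.109), with cyclic loess (0.107) and without the high-CO2 replicate 1 (0.103) or the 24 h replicate 2 (0.102) in the wild type. In the mutant it was 0.115 with normexp, 0.154 with quantile, 0.159 with median scaling and 0.122 with cyclic loess. It was also 0.126 without the filter on dim probes, 0.123 with slide or scan day as a fixed block, 0.105 with slide as a random block and 0.115 without the mutant high-CO2 replicate 1. Features near the background limit the depth: 520 could not be tested.

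A change of at least 1 on the log2 scale left 1603 features in the wild type at 3 h, 1920 at 24 h and 501 between them, and 757, 2347 and 1130 in the mutant. Slide as a fixed block gave 560 between 3 and 24 h in the wild type, 765 in the mutant at 3 h, 30, 26 and 26 between the strains at high CO2, 3 h and 24 h, and 3 and 0 differing responses. Scan day gave 21, 156, 43, 31, 29, 2 and 0 for the same results. The compared groups alone gave 1821 in the wild type at 3 h, 0 between 3 and 24 h, 28 in the mutant at 3 h, 1915 between 3 and 24 h, 0 and 217 between the strains at 3 h and 24 h, and 1 and 53 differing responses. Array weights gave 709 between 3 and 24 h in the wild type, 789 in the mutant at 3 h, 1266 between 3 and 24 h, 101, 16 and 876 between the strains, and 62 differing responses at 24 h. Without both 3 h arrays numbered 2 the counts were 2799 between 3 and 24 h in the wild type, 4001 in the mutant at 3 h, 145 and 584 between the strains at 3 h and 24 h, and 49 and 53 differing responses. The stricter filter gave 42, 38 and 61 between the strains. Normexp and the submitters' values each gave 6 and 4 differing responses. With a replicate block, tried although no pairing of cultures is stated (arrays of equal number share a slide in some groups, and their deviations correlate at 0.00157 to 0.618), 4 of the 15 at 24 h remained in number. These settings and the others in the methods changed no other count by over 1.5 times.

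Leaving out 1 array gave 2081 to 4034 features in the wild type at 3 h, 2251 to 4349 at 24 h and 233 to 2109 between them. In the mutant it gave 594 to 3112, 3362 to 5259 and 1753 to 4091. Between the strains it gave 45 to 78 at high CO2, 47 to 1573 at 3 h and 53 to 171 at 24 h, and differing responses numbered 5 to 323 and 0 to 40. A group left with 1 array was assumed to vary like the others.

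The direction of a called value or test turned as follows. For ccmK2 (sll1028) in the wild type at 3 h, normexp gave 0.0174, quantile scaling 0.0522 and the submitters' values 0.00698. Without both 3 h arrays numbered 2, cmpA (slr0040), flv4 (sll0217), flv2 (sll0219) and cpcB (sll1577) stood at −0.94, −0.83, −0.56 and 0.68 between 3 and 24 h in the mutant. For sbtA (slr1512) between the strains at 3 h the value was 1.29 without the mutant 3 h replicate 2 and −1.97 without replicate 1. List medians between the strains at 3 h, given first without replicate 2 and then without replicate 1 of the mutant 3 h arrays, were 0.47 and −7.55 for BCT1, −0.13 and 1.98 for NtcA-activated genes, −0.11 and 1.09 for chlorophyll synthesis, 0.10 and −1.15 for the NDH-1 core and −0.30 and 1.75 for photosystem I. Those of the differing responses were 0.57 and −7.43 for BCT1, −0.0911 and 2.07 for NtcA-activated genes, −0.13 and 1.13 for chlorophyll synthesis, 0.0744 and −1.18 for the NDH-1 core and −0.19 and 2.32 for the phycobilisome. Without both 3 h arrays numbered 2 the NDH-1 core stood at 0.0727 between the strains and 0.0373 in the differing responses, and BCT1 at 0.0642 in the latter. Scan day gave −0.0783 for the NDH-1 core between the strains. The phosphate list stood at −0.14 in the 24 h difference of responses and −0.0309 between the strains at high CO2 without the wild-type high-CO2 replicate 2, and at 2.07 and −2.26 without replicate 1. The plasmid pSYSA list between the strains at high CO2 stood at −0.0308 without replicate 1 and −0.248 without replicate 2. The high-CO2 medians of both lists kept their sign, and the turn was relative to the other mRNAs. The reverse held for medians that crossed 0 while the test kept its direction: phycobilisome between the strains at 3 h without the mutant replicate 2 (−0.0681), photosystem I between 3 and 24 h in the wild type with scan day as a block (−0.0685), phosphate there with slide as a block (0.0139) and in the wild type at 3 h without the high-CO2 replicate 1 (−0.0456), and NdhR-linked genes between 3 and 24 h in the mutant without the 3 h replicate 1 (−0.0797).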

Other observations

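Transcripts other than mRNAs also differed between the low-CO2 and high-CO2 groups, and no test here was run on their function. At 24 h antisense features were higher more often than lower in the wild type, 476 against 163, and in the mutant, 678 against 221. Non-coding RNAs stood at 159 higher and 89 lower in the wild type and 210 and 130 in the mutant. NC-1134 and NC-425 were 7.69 ± 0.86 and 7.31 ± 0.82 higher at 24 h in the wild type and 7.55 ± 0.78 and 7.40 ± 0.75 higher in the mutant. Of 42 rRNA, tRNA and small stable RNA features, limma called 28 higher and 0 lower in the mutant at 24 h (median 0.54), and 0 in the wild type (median 0.02), where 0 had an unadjusted p below 0.05. Between the strains at 24 h limma called 0 of them (median 0.52), with 32 at an unadjusted p below 0.05, and 0 in the difference of responses (median 0.52), with 5. The 75th percentile used for scaling was 7084 and 6532 in the mutant at high CO2 and 5271, 4683 and 4157 at 24 h. In the wild type it was 7245 and 5969, then 5911 and 7313. A lower percentile raises the scaled value of a feature whose brightness stays equal. The mutant's rise and the gap between the strains therefore do not show a change in the amount of stable RNA. NC-240 was at least 47.4-fold lower at 24 h than at high CO2 in the mutant.

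The feature us29-0-x, chosen after its values were seen, lay between −5.57 and −3.87 on the 4 high-CO2 arrays and between 5.85 and 7.21 on the low-CO2 arrays with a value, except the mutant 3 h replicate 2, where it lay at −4.46. The mutant 3 h replicate 1 had no usable spot for it.

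In the mutant 3 h replicate 2 the high-light inducible list stood at −0.81 relative to the mutant's high-CO2 mean, against 2.08 in replicate 1. The wild-type 3 h arrays parted in the same way, at 1.88 in replicate 1 and −0.67 in replicate 2. The correlation of this array across features, which are not independent replicates, was 0.952 and 0.956 with the mutant high-CO2 arrays and 0.912 with its own replicate.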
